A study of Homo sapiens with 6 samples.

How the data were processed

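SMAD2/3 ChIP-seq libraries of Hs578T and BT549 cells treated with TGFβ3 for 1.5 h or 16 h were compared, 4 libraries in all, with 1 per cell line and time. The series also has 2 input DNA samples, 1 per line, labelled untreated, which were not analysed here. Per the labels' protocols, chromatin was sonicated, precipitated with an antibody against SMAD2/3, made into libraries with an Ion Torrent fragment library kit, amplified by PCR and size selected on a gel. Per the submitters' processing notes, Bowtie 1.1.0, Picard and MACS 1.4.2 were used with the hg19 build. The role of Picard, the use of the input as background and any further setting are not given in the sources used here.

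The deposited files are peak lists, 1 per library, so the authors called peaks per sample and not on pooled samples. Each peak has a chromosome, a start, an end, a name and a score that the authors' peak caller assigned. MACS of this version writes 10 times the negative log10 of the p-value as its score; the lowest scores, 50.01 to 50.02, and the threshold of 1e-05 in the file names both fit that scale. The score depends on read depth as well as on enrichment, so it was used to describe, rank or filter the peaks of each list. Where the same score limit was applied to several lists, the counts past it depend on the depth of each library. Read totals and signal tracks were not used here; the depth behind each list is unknown, and a difference in the number of peaks between libraries can come from depth alone.

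Peak positions were read as deposited and are given from 1. A peak was counted as overlapping another list when it shared at least 1 bp with any of its peaks; the share is given per direction with a 95% Wilson interval. No test between conditions was made and no p-value is given. For the overlap that position alone gives, each peak of a list was placed at random on its own chromosome, keeping its width, in 1000 draws with a fixed seed. Chromosome ends were taken as the end of the last peak in any list. In an alternative, peaks were moved by 50 kb to 1 Mb to either side, which keeps the regional density. Regions of all 4 libraries came from merging peaks that touched, and the time classes of regions present in both lines were compared with 10000 shuffles. The overlap code was tested on simulated lists of the same sizes; in each of the 4 comparisons 200 of 200 planted shared peaks were recovered.

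The rule for the peaks named in the text, set before the data were examined, takes from each comparison the 5 highest-score peaks in both lists, ordered by the worse of both ranks, and the 5 highest-score peaks of each list without overlap in the other. For a shared site the span covering both peaks is given. Other places named, such as the dense windows, were chosen after their values were seen. Alternatives set before the data were examined were a score of at least 100, an overlap of 50% of both peaks, peaks within 500 bp, equal numbers of highest-score peaks, the local shift, and autosomes with chromosome X. Added after seeing the data were the removal of peaks within 1 Mb of the edges of the largest stretch without peaks on each chromosome (here called gap edges), the removal of dense 1 Mb windows, and the removal of peaks under 150 bp.

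An hg19 annotation and sequence were not used here, so shares of peaks in promoters, genes near peaks, the gene lists drawn up beforehand and the AP-1, SMAD, TEAD, RUNX, FOX and ETS motif shares were not computed, and peaks are named by position. The gene table at hand is on another build, and its coordinates were not used. Calculations were done in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1, and plots with matplotlib 3.10.9.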

Results

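Binding of SMAD2 and SMAD3 was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in Hs578T and BT549, 2 established human triple-negative breast cancer lines. SMAD2 and SMAD3 are the transcription factors that the TGFβ receptor phosphorylates, and the antibody recognises both. Cells of each line were stimulated with TGFβ3 and collected at 1.5 h and at 16 h, with 1 library per line and time and therefore no replicates. No difference between conditions was tested, and differences are given as the values of these libraries. The question posed by the design is where SMAD2/3 binds in each line early and late after TGFβ. The input DNA samples, 1 per line, were not analysed here. The peak lists carry no read totals, so sequencing depth is unknown.

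The lists held 1373 peaks for Hs578T at 1.5 h, 1849 for Hs578T at 16 h, 9225 for BT549 at 1.5 h and 8153 for BT549 at 16 h. Positions are on hg19, and each score is the authors' own peak-caller value, used here to rank and filter the peaks of a list. What a given score stands for depends on the depth of its library, so counts above a score limit are not a measure of equal enrichment in different lists. Median peak width was 141 bp and 151 bp in Hs578T at 1.5 h and 16 h, and 238 bp and 240 bp in BT549. Peaks covered 229 kb and 376 kb of the genome in Hs578T, against 2621 kb and 2295 kb in BT549. A score of 100 or more was reached by 12.0% of the Hs578T 1.5 h peaks (10.4 to 13.8, 95% Wilson interval) and 18.9% of the 16 h peaks (17.2 to 20.8). In BT549 the shares were 41.9% (40.9 to 42.9) at 1.5 h and 33.4% (32.4 to 34.5) at 16 h. Intervals here and elsewhere cover counting error only. From 1.5 h to 16 h the number of peaks was 1.35 times as high in Hs578T and 0.884 times as high in BT549.

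**Figure D1:**
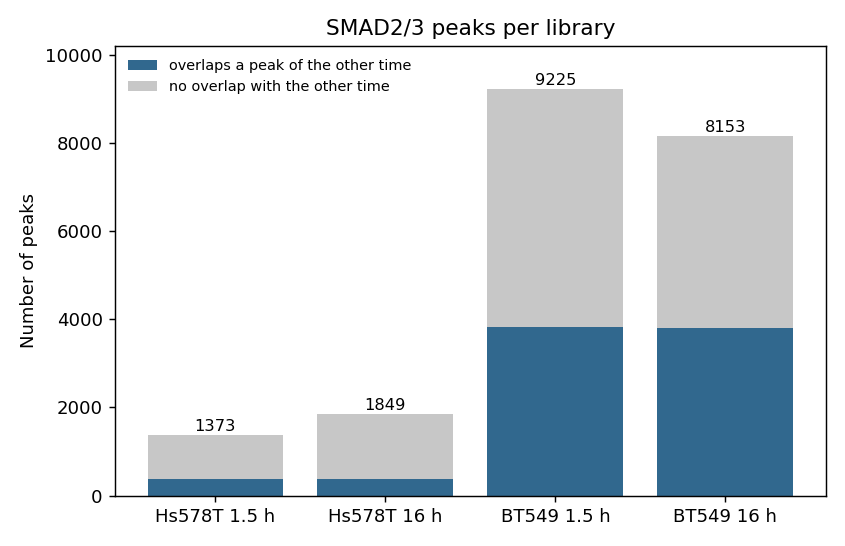
Number of SMAD2/3 peaks in each of the 4 libraries, split into peaks that overlap a peak of the other time in the same cell line by at least 1 bp and peaks that do not. The bars reach 1373 and 1849 peaks in Hs578T and 9225 and 8153 in BT549.

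In Hs578T, nearly all of the strongest SMAD2/3 sites were occupied at both times, while most of the weaker peaks were listed at only 1 of them. The highest-scoring peak of both lists lay on chromosome 7 from 27219472 to 27220309, with scores of 782.5 at 1.5 h and 1498 at 16 h. It was followed in both lists by chromosome 1 from 3309541 to 3310722, with scores of 724.3 and 1485. A pair of sites on chromosome 10, from 74020229 to 74021316 and from 74032268 to 74033157, and a site on chromosome 2 from 176968505 to 176969362 completed the 5 leading shared regions. Of the 1.5 h peaks, 382 of 1373 overlapped a 16 h peak, or 27.8% (25.5 to 30.3). Of the 16 h peaks, 371 of 1849 overlapped a 1.5 h peak, or 20.1% (18.3 to 22.0). Random placement of the 1.5 h peaks on their own chromosomes gave a mean of 0.305 overlaps and at most 3 in 1000 draws.

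Among the 100 highest-scoring Hs578T peaks, 98.0% (93.0 to 99.5) of those at 1.5 h and 92.0% (85.0 to 95.9) of those at 16 h overlapped a peak of the other time. Among the 1000 highest-scoring peaks these shares were 33.6% and 32.9%. Peaks found at 16 h without a 1.5 h peak were led by chromosome 18 from 13447604 to 13448010, with a score of 380.0, and chromosome 7 from 80506173 to 80506777, with 367.1. A region on chromosome 7 from 27645793 to 27646249 scored 325.3, chromosome 1 from 177312470 to 177312887 scored 320.6, and chromosome 2 from 177023549 to 177023916 scored 285.1. Of the 350 peaks at 16 h with a score of 100 or more, 126 had no 1.5 h peak. Of the 165 such peaks at 1.5 h, 18 had no 16 h peak.

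The leading 1.5 h peaks without a 16 h peak in Hs578T were on chromosome 1 from 121484271 to 121485434, with a score of 433.8, and on chromosome 7 from 61969202 to 61969576, with 182.4. They were followed by chromosome 8 from 124667054 to 124667115 with 132.2, chromosome 1 from 91852783 to 91853147 with 116.8, and chromosome 6 from 58777061 to 58779371 with 115.2. The regions of chromosome 1 from 121484271, chromosome 7 from 61969202 and chromosome 6 from 58777061 lie within 1 Mb of the edge of the largest stretch without peaks on their chromosome, here called a gap edge. The same 3 places held peaks in BT549. The share of 1.5 h peaks found again at 16 h was 78.2% when both lists were limited to scores of 100 or more, and 16.3% when 50% of both peaks had to overlap. Without peaks under 150 bp, a limit chosen after seeing the data, it was 54.8%.

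In BT549, the leading sites were likewise held at both times. Beside 2 gap-edge regions, on chromosome 1 from 121484054 to 121485466 and on chromosome 7 from 61968620 to 61969728, the strongest shared site was on chromosome 17 from 48255123 to 48256219, with scores of 2234 at 1.5 h and 1913 at 16 h. It was followed by chromosome 5 from 64331168 to 64332055, with 1702 and 1445, and chromosome 4 from 166501285 to 166502114, with 1429 and 1274. Of the 1.5 h peaks, 3817 of 9225 overlapped a 16 h peak, or 41.4% (40.4 to 42.4). Of the 16 h peaks, 3793 of 8153 overlapped a 1.5 h peak, or 46.5% (45.4 to 47.6). Random placement gave a mean of 15.2 overlaps and at most 30. The share of 1.5 h peaks found at 16 h lay above that of Hs578T over the whole lists, but below it with scores of 100 or more in both lists (42.1% against 78.2%) and without peaks under 150 bp (44.2% against 54.8%). Of 1.5 h peaks with a score of 100 or more, 64.0% against 89.1% overlapped a 16 h peak of any score. Of 1.5 h peaks of 150 bp or more, 44.7% against 56.6% overlapped a 16 h peak of any width. In the other direction BT549 lay above Hs578T. Of 16 h peaks with a score of 100 or more, 70.9% against 64% overlapped a 1.5 h peak of any score. Of 16 h peaks of 150 bp or more, 52.6% against 33.4% overlapped a 1.5 h peak of any width. Under these limits the order of the lines thus depends on the direction, while over the whole lists BT549 lay above in both directions. The longer list is that of 16 h in Hs578T but of 1.5 h in BT549. All of the 100 highest-scoring peaks of each time overlapped a peak of the other time (96.3% to 100%), and of the 1000 highest-scoring, 92.6% at 1.5 h and 89.5% at 16 h did.

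The leading BT549 peaks listed only at 1.5 h ranked 314 or lower in their list. They were on chromosome 1 from 51443068 to 51443707, with a score of 392.1, chromosome 3 from 67697882 to 67698341, with 384.0, and chromosome 6 from 74290123 to 74290757, with 332.2. Chromosome 1 from 59622532 to 59622859 and from 186799741 to 186799834 followed with 325.5 and 320.5. The leading peaks listed only at 16 h were on chromosome 5 from 13566949 to 13567494, with 250.6, chromosome 10 from 51110806 to 51110915, with 247.4, and chromosome 1 from 204390929 to 204391021, with 243.0. Chromosome 12 from 71968088 to 71968178 and chromosome 11 from 98604140 to 98604500 followed with 242.3 and 238.4. Of these 10 regions, 4 were 91 to 110 bp wide.

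**Figure D2:**
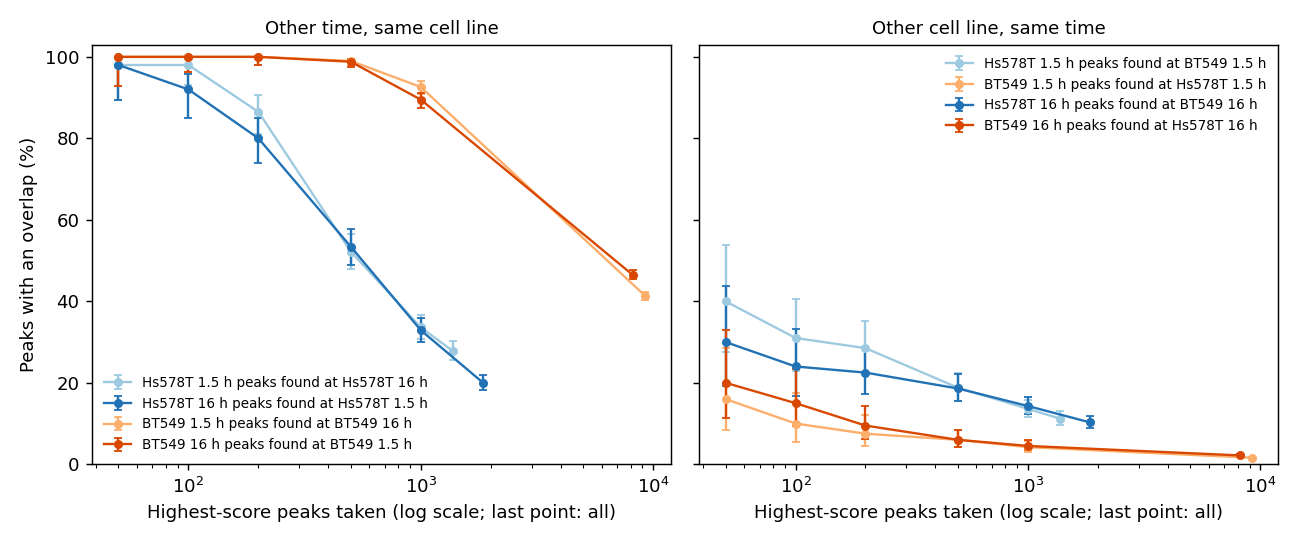
Percent of the highest-scoring peaks of each list, on the vertical axis, that overlap a peak of the other time (left) or of the other cell line (right), against the number of peaks taken on a log scale, with 95% Wilson intervals; the last point of each line is the whole list. For the 100 highest-scoring peaks the shares are 92.0% to 100% between times and 10.0% to 31.0% between lines.

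At scores of 100 or more, BT549 peaks under 150 bp recurred less often than wider ones. Among peaks with a score of 100 or more, 613 at 1.5 h and 617 at 16 h were under 150 bp wide, with median widths of 86 bp and 88 bp. Of these narrow peaks, 9.46% (7.39 to 12.0) at 1.5 h and 7.78% (5.92 to 10.2) at 16 h overlapped a peak of the other time. The wider peaks of the same score range overlapped in 74.2% (72.7 to 75.7) and 89.3% (87.9 to 90.6). Narrow peaks made up 555 of the BT549 1.5 h peaks with a score of 100 or more and no 16 h overlap, or 39.8%, and 569 of those at 16 h, or 71.7%. The remaining 838 at 1.5 h and 225 at 16 h were wider. At scores from 50 to 75 the order at 1.5 h was the opposite, with 32.6% (26.7 to 39.0) of the narrow and 20.7% (19.3 to 22.2) of the wider peaks recurring, but not at 16 h, with 22.4% (18.4 to 27.0) and 29.8% (28.4 to 31.3). In Hs578T, 64.2% of the 1.5 h peaks and 47.6% of the 16 h peaks were under 150 bp, against 12.3% and 15.7% in BT549. Over all scores, 11.8% and 5.34% of the narrow Hs578T peaks overlapped the other time, against 56.6% and 33.4% of the wider ones. Only 10 and 14 narrow Hs578T peaks scored 100 or more. This split by width was made after seeing the data.

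**Figure D3:**
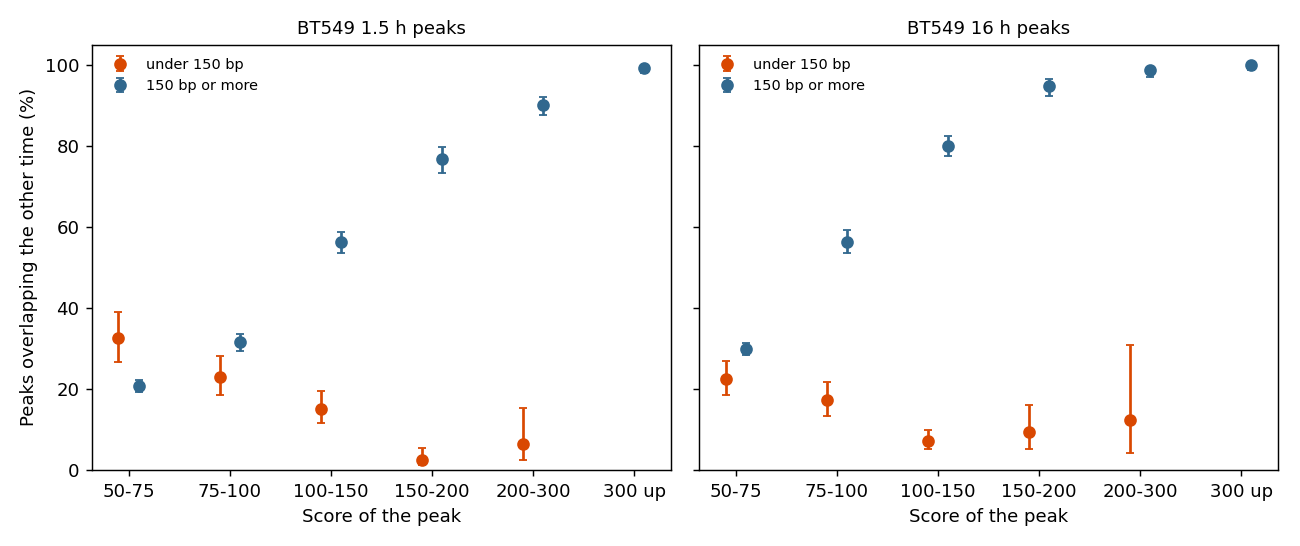
Percent of BT549 peaks that overlap a peak of the other time, by score class (horizontal axis) and for peaks under 150 bp and of 150 bp or more, with 95% Wilson intervals; classes with fewer than 20 peaks are not drawn. Overlap of the wider peaks rises with score at both times, while that of the narrow peaks at scores from 150 to 200 is 2.59% at 1.5 h and 9.40% at 16 h.

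At 1.5 h, a small part of the SMAD2/3 peaks listed in each cell line overlapped a listed peak of the other line. The leading shared sites outside the gap edges were on chromosome 10 from 74078964 to 74079748, with scores of 360.2 in Hs578T and 1434 in BT549, and on chromosome 3 from 5019964 to 5021065, with 292.0 and 668.4. Chromosome 20 from 56284876 to 56285640 followed with 193.1 and 624.1. The gap-edge regions of chromosome 1 (from 121484271) and chromosome 7 (from 61968742) were also shared. Of the Hs578T peaks, 154 of 1373 overlapped a BT549 peak, or 11.2% (9.65 to 13.0), against a mean of 1.90 and at most 7 under random placement. In the other direction, 147 of 9225 BT549 peaks overlapped a Hs578T peak, or 1.59% (1.36 to 1.87).

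The 2 highest-scoring Hs578T sites at 1.5 h had no BT549 peak. The Hs578T peaks without one on chromosome 7 from 27219611, chromosome 1 from 3309775 and chromosome 2 from 176968692 lie within regions named above, and they were joined by chromosome 10 from 77164631 to 77165388, with a score of 572.5, and chromosome 7 from 27227222 to 27227688, with 364.2. Conversely, BT549 peaks without a Hs578T peak at 1.5 h were led by chromosome 17 from 48255253 to 48256168, with 2234, and chromosome 8 from 23398269 to 23399726, with 2152. The chromosome 17 site lacked a Hs578T peak at 1.5 h only. At 16 h its BT549 peak, which ranked 2 with a score of 1913, overlapped a Hs578T peak. Chromosome 5 from 64331168 to 64331875, chromosome 19 from 13961887 to 13962690 and chromosome 8 from 103818481 to 103819581 followed with 1702, 1516 and 1344. With only as many BT549 peaks as Hs578T peaks taken, by score, the shared part was 3.71% of the Hs578T list. With scores of 100 or more in both lists it was 21.8%, and with 50% of both peaks overlapping it was 5.32%.

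At 16 h, the shared sites of the lines were led by the same place on chromosome 10, from 74079063 to 74080120, with scores of 500.5 in Hs578T and 1001 in BT549. Chromosome 3 from 71560128 to 71560759 followed with 603.6 and 750.2, chromosome 3 from 5019887 to 5021064 with 304.9 and 615.5, chromosome 18 from 46478507 to 46479334 with 433.0 and 504.8, and chromosome 9 from 132250827 to 132251716 with 231.6 and 1006. Of the Hs578T peaks, 190 of 1849 overlapped a BT549 peak, or 10.3% (8.97 to 11.7), against a mean of 2.46 and at most 10 under random placement. Of the BT549 peaks, 177 of 8153 did so, or 2.17% (1.88 to 2.51).

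Hs578T peaks at 16 h without a BT549 peak were again led by the sites on chromosome 7 from 27219472, chromosome 1 from 3309541 and chromosome 2 from 176968505. Chromosome 5 from 159139581 to 159140113 and chromosome 4 from 112804615 to 112805136 came next, with 805.3 and 768.3. In BT549, the leading peaks without a Hs578T peak included the gap-edge regions of chromosomes 1, 7 and 6, of which the last spans 58776450 to 58779378. The others were chromosome 17 from 76588284 to 76589058, with 1609, and chromosome 5 from 64331260 to 64332055, with 1445. With equal numbers of peaks taken by score, 4.16% of the Hs578T list was shared, and with 50% of both peaks overlapping 5.30% was. With scores of 100 or more in both lists the shared part was 11.1%.

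Overlap between the lines was also counted across times, on lists of unequal length and without a test of the differences. Hs578T 1.5 h peaks overlapped the BT549 16 h list in 9.90% (8.44 to 11.6), against 11.2% for the BT549 1.5 h list. Hs578T 16 h peaks overlapped the BT549 1.5 h list in 10.8% (9.43 to 12.3), against 10.3% for the BT549 16 h list. BT549 1.5 h peaks overlapped the Hs578T 16 h list in 2.05% (1.78 to 2.36), against 1.59% for the Hs578T 1.5 h list. BT549 16 h peaks overlapped the Hs578T 1.5 h list in 1.58% (1.33 to 1.88), against 2.17% for the Hs578T 16 h list.

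Merging all peaks that touched gave 15870 regions, of which 2792 were occupied in Hs578T and 13389 in BT549. A peak of both lines was present in 311 regions, and 65 regions had a peak in all 4 libraries. Ordered by their worst rank in any list, these 65 were led by chromosome 10 from 74078964 to 74080120, which ranked 12, 26, 7 and 13 in Hs578T at 1.5 h and 16 h and BT549 at 1.5 h and 16 h. Next came chromosome 3 from 5019864 to 5021065, chromosome 18 from 46478155 to 46479465, chromosome 3 from 71560128 to 71560759 and chromosome 1 from 234748127 to 234749051. The number was 19 at scores of 100 or more, 21 when 50% of both peaks had to overlap, and 26 with equal numbers of peaks per list. Of the 65 regions, 3 lay within 1 Mb of a gap edge.

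Among the 311 regions of both lines, the times at which a region had a listed peak were compared between lines. Peaks at both times in both lines were listed for the 65 regions above, against 53.5 expected from the margins and 45 to 62 in 95% of 10000 shuffles of the region labels. Peaks only at 1.5 h in both lines were listed for 23 regions, with 19.8 expected and a range of 13 to 26. Peaks only at 16 h in both lines were listed for 34, with 29.1 expected and a range of 22 to 36. The shuffles treated each region as independent, though some lie side by side, such as chromosome 1 from 875720 to 876689 and from 876767 to 877439. They did not hold peak strength fixed, and a peak absent from a list may be a missed call. Shared timing of binding between the lines was therefore not tested.

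A small part of the Hs578T peaks was crowded into short stretches of the genome. In 5 windows of 1 Mb, singled out after their counts were seen, both Hs578T lists had 10 or more peaks. The window of chromosome 7 from 27000001 to 28000000 held 23 peaks at 1.5 h and 25 at 16 h, that of chromosome 8 from 37000001 to 38000000 held 15 and 23, and that of chromosome 12 from 54000001 to 55000000 held 16 and 19. Chromosome 17 from 46000001 to 47000000 held 14 and 21, and the start of chromosome 1, up to 1000000, held 15 and 12. In that chromosome 1 window most peaks of each library, in both lines, were closely spaced calls between 875011 and 880373. Its count is therefore not a count of separate sites, nor is the crowding there particular to Hs578T. Together they held 6.05% (4.90 to 7.43) of the Hs578T peaks at 1.5 h and 5.41% (4.47 to 6.53) at 16 h, but 0.390% (0.282 to 0.540) and 0.491% (0.361 to 0.667) of the BT549 peaks. In them BT549 had a mean of 7.20 peaks at 1.5 h and 8 at 16 h, against 3.02 and 2.67 per window genome-wide. The window of chromosome 12 had 11 and 13 BT549 peaks. Windows just short of the limit differed in their BT549 peaks. That of chromosome 2 from 176000001 to 177000000 held 8 and 9 Hs578T peaks and no peak in either BT549 list. Chromosome 10 from 77000001 to 78000000 held 9 and 18 Hs578T peaks and 5 and 3 BT549 peaks. Chromosome 1 from 3000001 to 4000000 held 8 and 8 Hs578T peaks and 11 and 8 BT549 peaks.

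**Figure D4:**
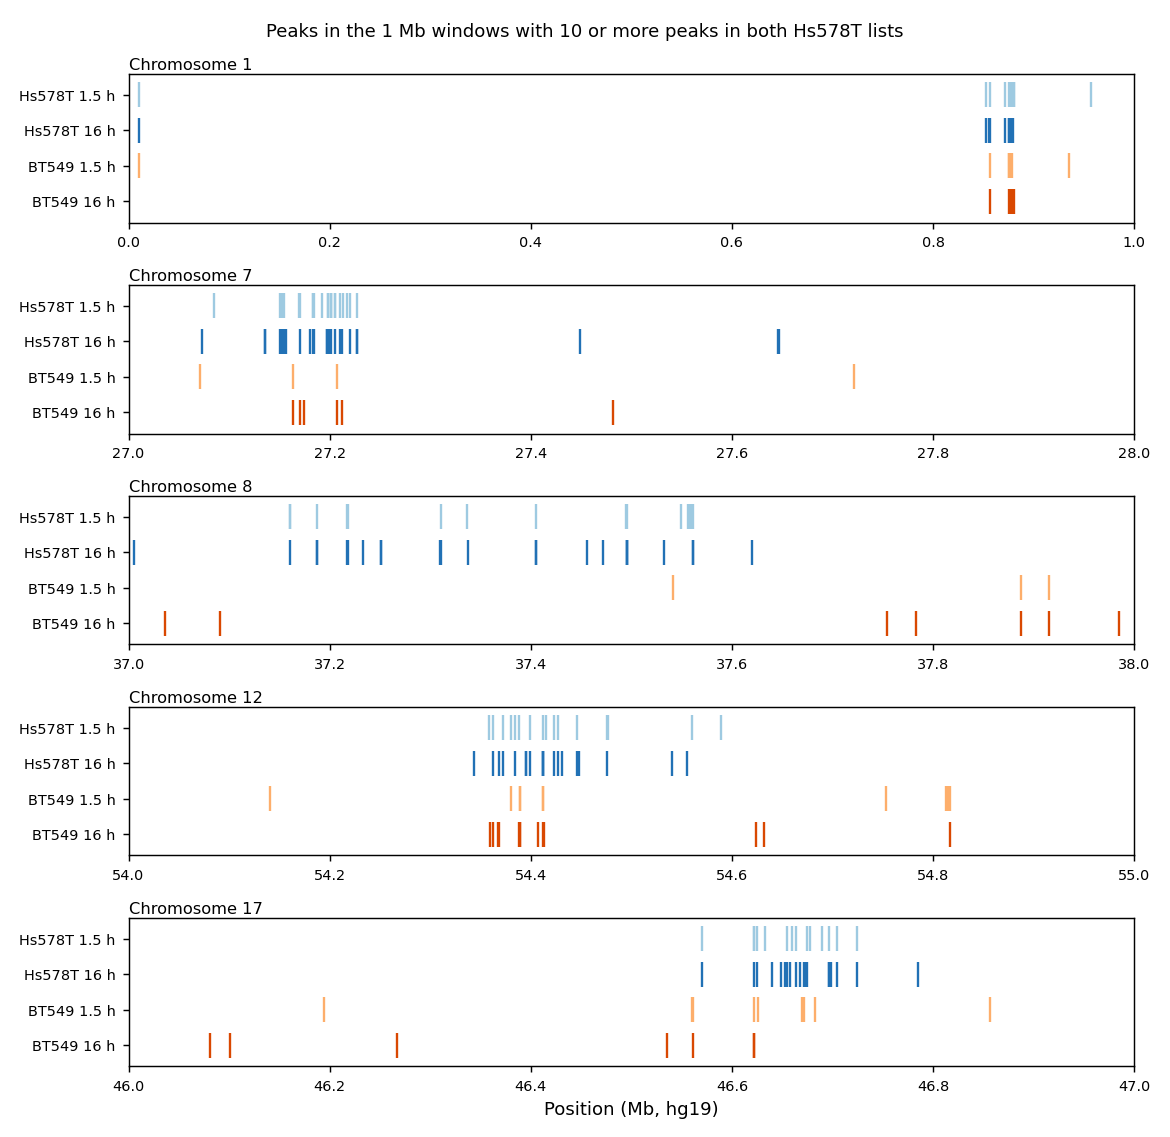
Positions (horizontal axis, Mb on hg19) of the SMAD2/3 peaks of the 4 libraries in the 5 windows of 1 Mb with 10 or more peaks in both Hs578T lists; each tick is the middle of a peak and each line of ticks is a library. In the window of chromosome 7, 23 and 25 Hs578T peaks stand beside 4 and 6 BT549 peaks.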

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

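The test of the highest-scoring peaks described here was chosen after the result was seen. From 1.5 h to 16 h, Hs578T and BT549 moved in opposite directions in each of 3 counts of SMAD2/3 occupancy; the difference was not tested, since each line has 1 library per time. The number of peaks at 16 h was 1.35 times that at 1.5 h in Hs578T and 0.884 times in BT549. For peaks with a score of 100 or more the ratios were 2.12 and 0.705, and for the length of genome covered 1.64 and 0.876. The depth of each library, which is unknown, enters all of these counts, the score limit included.

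At both times the Hs578T lists were the shorter ones, and BT549 had 6.72 times as many peaks at 1.5 h and 4.41 times as many at 16 h. If the Hs578T lists were a shallower sample of the sites in the BT549 lists, most of their strongest peaks would lie in BT549 peaks. Of the 100 highest-scoring Hs578T peaks, 24% (16.7 to 33.2) at 16 h and 31.0% (22.8 to 40.6) at 1.5 h did so, which argues against that explanation. Fewer reads or weaker enrichment in Hs578T, at sites of its own, may have shortened its lists; with no read totals, this and a smaller number of occupied sites in Hs578T cannot be told apart from the 6.72-fold ratio. A difference between the cell lines in SMAD2/3 occupancy remains open and untested.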

How the results depend on the processing

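Alternatives without gap edges, dense windows or peaks under 150 bp were chosen after seeing the data; the cause of each shift was not tested. The order of the libraries by number of peaks was the same at scores of 100 or more, with 165 and 350 peaks in Hs578T and 3866 and 2726 in BT549 at 1.5 h and 16 h, and without peaks under 150 bp, when Hs578T had 491 and 969. The share of Hs578T 1.5 h peaks found at 16 h, 27.8%, became 78.2% at scores of 100 or more, 16.3% with 50% of both peaks overlapping, 54.8% without peaks under 150 bp and 25.04% without dense windows. Its ratio to random placement, 1252, fell to 499 under local shifts. In BT549 the share, 41.4%, became 32.5% with 50% of both peaks, 46.2% within 500 bp, 43.9% with equal numbers and 44.2% without peaks under 150 bp. Between lines at 1.5 h, 11.2% became 21.8% at scores of 100 or more, 5.32% with 50% of both peaks, 13.2% within 500 bp, 3.71% with equal numbers and 18.9% without peaks under 150 bp. Between lines at 16 h, 10.3% became 5.30% with 50% of both peaks, 4.16% with equal numbers and 12.6% without peaks under 150 bp. At scores of 100 or more it was 11.1%, so the rise seen at 1.5 h with that limit was not seen at 16 h. The 65 regions of all 4 libraries became 19 at scores of 100 or more, 21 with 50% of both peaks and 26 with equal numbers. Leaving out gap edges kept each overlap share within its interval. Under each alternative run, the share between times in a line stayed above that between lines at the same time. Promoter shares, gene lists and motif shares were not run. Unknown depth limits any reading of the number of peaks or of a peak's absence from a list.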

Other observations

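The tests here were chosen after the result was seen, except the random placements of peaks in windows and of narrow peaks around the sites of the other time; the local shifts of narrow peaks and the chromosome shares without dense windows were also added after seeing the data. The densest windows of the BT549 lists were not those of Hs578T. The window of chromosome 9 from 132000001 to 133000000 held 27 BT549 peaks at 1.5 h and 22 at 16 h, against 3 and 2 in Hs578T, and that of chromosome 11 from 65000001 to 66000000 held 21 and 26, against 1 and 3. In 1000 random placements no window held more than 18 peaks of the BT549 1.5 h list or 17 of the 16 h list. At 1.5 h the shares of peaks per chromosome had intervals apart between the lines on 10 chromosomes. The share was higher in BT549 on chromosomes 5, 8, 9 and 20, and higher in Hs578T on chromosomes 1, 2, 7, 15, 17 and X. Chromosome 20 carried 2.99% (2.66 to 3.36) of the BT549 and 1.02% (0.608 to 1.70) of the Hs578T peaks, and chromosome 8 carried 8.04% (7.51 to 8.62) and 3.93% (3.03 to 5.10). Chromosome X carried 6.12% (4.97 to 7.51) of the Hs578T and 2.35% (2.06 to 2.68) of the BT549 peaks. At 16 h the intervals were apart on 11 chromosomes, with BT549 higher on 5, 6, 8, 9 and 11 and Hs578T higher on the same 6 as at 1.5 h. Without the 5 dense windows, chromosomes 7 and 17 were no longer apart at 1.5 h; at 16 h chromosomes 6 and 17 were no longer apart and chromosome 10 was, with Hs578T higher. Peaks within 1 Mb of a gap edge were 2.48% and 1.14% of the Hs578T lists and 1.82% and 2.20% of the BT549 lists at 1.5 h and 16 h.

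For the 5 dense Hs578T windows, 3 technical explanations were tested. Chance clumping of evenly spread peaks is argued against, since the highest window count in 1000 random placements was 8 in either Hs578T list. A copy number gain or raised background that alone gave such counts over a longer segment would fill the neighbouring windows too. The median ratio of neighbouring to dense window counts was 0 in both lists. The windows beside that of chromosome 7 held a mean of 1 peak at 1.5 h and 3 at 16 h. With 0.449 and 0.604 Hs578T peaks per window genome-wide, a gain of a few fold could leave neighbours this sparse. The ratio therefore cannot exclude a contribution from a longer gain or raised background, and a gain shorter than 1 Mb was not tested. A sequence property that gives as many calls in any library is argued against over the set: the same 5 windows come from the Hs578T 1.5 h list alone, and at 16 h they held 40 BT549 peaks (28.6 to 54.5, exact Poisson) against 100 in Hs578T (81.4 to 122). Peaks in a window are not independent, BT549 was above its own genome-wide mean there, and chromosome 12 held 13 against 19. A property that gives calls unevenly between libraries, a copy number gain or raised background, and a difference between the lines therefore all stay open.

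Whether peaks listed at 1 time only are mostly sites near the calling threshold was not settled. Of the 100 highest-scoring 16 h peaks, 92.0% in Hs578T and 100% in BT549 had a 1.5 h peak, as that account predicts. These strongest peaks cannot tell a missed weak site from one bound at 1 time only. Some peaks with a score of 100 or more were also listed at 1 time only. They include 126 of 350 Hs578T 16 h peaks, 82 of them with scores from 100 to 150. In BT549 they include 838 of 3253 peaks of 150 bp or more at 1.5 h. Since scores depend on depth, such a score in 1 list can lie near the limit of the other, so these counts do not decide either. The threshold account is argued against for narrow BT549 peaks. At scores from 150 to 200, 2.59% (1.19 to 5.53) of those at 1.5 h recurred, below the 32.6% (26.7 to 39.0) at scores from 50 to 75. What gave rise to the narrow peaks, stacked PCR copies included, was not tested. By the bounds set beforehand, random placement of the non-recurring narrow peaks with a score of 100 or more was not rejected. Of these peaks, 7.93% (5.96 to 10.5) at 1.5 h and 8.44% (6.42 to 11.0) at 16 h lay within 10 kb of a peak of the other time. The lower ends of the intervals did not pass 2 times the mean of the random placements, 4.75% and 5.17%, and lay below their highest values, 7.75% and 8.08%. The shares themselves lay above all of 1000 random placements. They also lay above all but 14 and 10 of 1000 local shifts, which had means of 5.47% and 5.94%. That comparison was read after the result was seen and both directions use the same pair of lists, so the question stays open. Of the wider non-recurring peaks in this score range, 32.0% at 1.5 h and 31.6% at 16 h lay within 10 kb.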
